A study of Caenorhabditis elegans with 2 samples.

How the data were processed

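Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out against AMA-1, the large subunit of RNA polymerase II, in early embryos of the Caenorhabditis elegans wild-type strain N2. Whole embryos of pooled sexes were used. The 2 samples are biological replicates 1 and 2 of 1 group, each from its own biosample, with a size range of 150 to 350 given in the labels. No second condition enters the design, so tests compare peaks with shifted peaks, gene groups with other genes, peak counts with chromosome length, upper with lower peaks, or 1 replicate with the other. A single control served both replicates per the deposited text notes, and it was not analysed here.

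Peak lists were made by the authors on the genome builds ce10 and ce11. Each build has a list of 30000 peaks per replicate, a list of 30000 peaks called on both replicates pooled, and an optimal list. The long lists are relaxed lists that include background and served as input to the irreproducible discovery rate (IDR) procedure. That procedure weighs how alike peaks rank between lists, and an optimal peak can still rank unlike in the replicates. The optimal lists hold 724 peaks on ce11 and 812 on ce10 and are IDR-thresholded per the deposited text notes. When checked against the pooled lists, they held the 724 and the 812 pooled peaks of highest signal. The signal value of each peak is the authors' own, and its scale is not given in the sources used here, so the deposited signal was used only to rank peaks within a list. The deposited lists also give a −log10 q-value per peak, which took the single value 3.58 throughout the optimal lists and was not used for ranking. The aligner, the peak caller and the IDR threshold are not given in the sources used here. Read depth is unknown, since the lists carry no read counts. The number of peaks, not the number of reads, sets the intervals given below. Most peaks have a fixed width: 555 of the 724 optimal peaks are 370 bp wide.

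Positions were taken as the files give them, counted from 1, and coordinates were never converted between builds. Genes came from Ensembl release 115 for WBcel235, the sequence of ce11. No ce11 peak ran past the end of its WBcel235 chromosome. The gene models gave 19973 protein-coding genes on the nuclear chromosomes. Their annotated 5' ends are often trans-splice sites and not transcription starts in this species. A gene was called bound when a summit lay between 500 bp upstream of its 5' end and its 3' end. A summit in the windows of several genes was credited to each of them, and a noncoding RNA gene was called bound by a summit within 200 bp.

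The share of replicate 1's top 724 peaks that overlapped replicate 2's top 724 by at least 1 bp was tested with a one-sided permutation that shifted all peaks along each chromosome, circularly, 10000 times. The smallest p these shifts can give is 1.00e-04 one-sided and 2.00e-04 two-sided. Optimal peaks were looked up among the 5000 highest peaks of each replicate. Spearman's rho of signal was computed over overlapping peaks in the upper 5000 of both replicates. Summit positions, gene ends within 250 bp and noncoding RNA genes were tested with two-sided circular shifts. Summit classes were assigned in the order upstream (within 500 bp of a 5' end), exon (5' UTR or coding), intron, 3' UTR, downstream (within 500 bp) and other. Chromosome shares were tested with exact binomial tests. Gene lists were tested with two-sided Fisher's exact tests against all other protein-coding genes. Benjamini-Hochberg adjustment was applied over the gene lists, over the noncoding classes and over the chromosomes. It was added for the summit classes too, although their calls rest on the unadjusted p. The threshold was 0.05, and intervals of shares are exact binomial 95% intervals that cover counting error only. The 95% interval of Spearman's rho came from Fisher's z transformation with a standard error for independent pairs.

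The gene lists covered early zygotic regulators, maternal and germline factors, histone genes, cytosolic ribosomal proteins, translation factors, proteasome subunits, respiratory chain and ATP synthase, heat shock and chaperones, cytoskeleton and cell junction, body wall muscle, intestine, neurons, collagen and cuticle, sperm, dosage compensation and sex determination, RNA polymerase II and general transcription, and cell cycle and mitosis. The groups, tests, windows, lists, most other settings and the rule for naming genes were fixed before the data were examined. That rule names genes in the windows of the 25 highest optimal peaks, up to 4 bound members per list by signal, and ama-1. Further names are said to have been chosen after their values were seen.

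Other settings chosen at the same time were a stricter list (362 peaks, the upper part of the optimal list), a looser one (the upper 2000 pooled peaks), each replicate's own top 724 peaks in place of the optimal list, merged peaks (693), other windows, other overlap rules, other gene assignments, draws matched on gene length in 10 bins, and the ce10 lists. Assignment to summits 100 to 500 bp past a 3' end, and removal of the 96 summits near noncoding RNA genes, were added after the data had been seen. No ce10 chromosome lengths were used: the ce10 X share is a share only, and the ce10 replicate overlap was shifted along WBcel235 lengths. Single-copy sequence was measured as the percentage of 31-mers that occur once in WBcel235, within 100 bp of a summit or over a gene and 100 bp on each side of it. For short genes much of the measured sequence is therefore flank. A gene with 50% or more such 31-mers is called mostly single-copy.

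The procedures were tested on simulated data with 724 summits and 19973 genes. Planted were 15 summits in genes of 1 list, 15 at miRNA genes, 100 upstream of genes and 60 past 3' ends, and 100 peaks in both of 2 sets. Each planted effect was called in 20 of 20 simulations, which says nothing about smaller effects. Simulated summits were placed independently and evenly along chromosomes, whereas some real peaks overlap. The counts of false calls therefore need not hold for the real peaks. With nothing planted, the list test made 7 false calls in 640 tests and the length-matched draws made 1. The shift tests made 2 false calls in 20 simulations each for upstream summits, 5' ends and summits past 3' ends, and 1 in 20 each for miRNA genes and shared peaks. The length-matched value is given beside each list called with gene windows, and none was computed for lists called past 3' ends. A peak list carries no error per peak, so no test was made on a single gene. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.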

Results

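AMA-1 occupancy was mapped in early embryos, the stage at which the embryo's own genome begins to be transcribed, in 2 biological replicates of a single group. The optimal list held 724 peaks on ce11, with signal values from 50.7 to 1410 and a median of 62.12. A summit fell in the window of 512 of 19973 protein-coding genes (2.56%), which took 603 of the peaks. A set of 96 peaks (13.3%) had their summit within 200 bp of a noncoding RNA or pseudogene locus of a tested class, some of them inside protein-coding windows too. Another 87 peaks lay in no protein-coding window and near no locus of a tested class, and many of these lay within 500 bp past the 3' end of a protein-coding gene, which the window leaves out. Several genes carried more than 1 summit: 93 had at least 2 and 24 at least 3. The cadherin gene of embryonic cell junctions, hmr-1, is 58913 bp long and had 6. Named after their values were seen, mnk-1, a kinase gene of 12624 bp, and unc-44, an ankyrin gene of 29301 bp, had 5 each. These counts make no allowance for gene length, and his-59, 411 bp long, had 4. Read depth is unknown and signal has no stated scale, so signal values are given only to rank peaks within the list.

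The highest AMA-1 peaks lay on short RNA genes and histone genes in both replicates. The peak at cel-mir-52, a microRNA gene on chromosome IV (peak 14033726 to 14034631), ranked 1 in the optimal list and in each replicate, with a signal of 1410. The next 3 peaks lay on sls-2.4 on I (821.4), sls-2.1 on II (565) and sls-2.2 on II (449.1), genes for the SL2 spliced leader RNA that is joined to messages of downstream operon genes. Of the 25 highest peaks, 9 lay near a tested noncoding gene and 6 in the window of a core or linker histone gene. All 25 ranked within the upper 100 of both replicates, at rank 43 or better in replicate 1 and 33 or better in replicate 2.

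Among these 25 peaks, the remaining noncoding genes were cel-mir-58a (IV, signal 312.4), which lies in an intron of Y67D8A.2, and sls-2.8 (III, 206.1), upstream of tim-1 and Y75B8A.23. They also included sup-39 with mir-1831 and the piRNA gene 21ur-14704 (II, 282.3), in an intron of C15F1.5, and sup-6 (II, 206), in an intron of F58G1.7. The annotation classes sup-39, mir-1831 and sup-6 as snRNA genes. The histone peaks lay on his-32 (H3; IV, exon, 403.9), his-59 and his-60 together (H3 and H4; IV, 270), his-24 (a linker histone; X, exon, 230.1), his-72 (an H3.3 variant; III, intron, 206.5), hil-3 (a linker histone; X, exon, 189) and his-31 (H4; IV, exon, 185.2). A further peak just past the 3' end of his-32 (IV, rank 24) overlapped the his-32 peak. The his-31 summit also lay 236 bp past the 3' end of lys-10. Other protein-coding genes in the set were tos-1 (V, exon, 312.9), Y43F8B.2 (V, exon, 291), mdt-26 with ift-43 (II, upstream, 280.1) and mdt-26 again (intron, 184.8), nurf-1 (II, exon, 260.1), cav-1 (IV, exon, 210.1) and T28B8.1 (I, exon, 185.6). The product of mdt-26 is a Mediator subunit, that of nurf-1 a chromatin remodelling subunit and that of cav-1 a caveolin. Summits at X 16930052 (430) and III 9765575 (241.8) lay in no protein-coding window and within 200 bp of no tested noncoding gene. The summit on III lay upstream of cbp-1, named after its values were seen. That gene starts at 9766509, which leaves the summit outside its 500 bp window.

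The mir-35 cluster on chromosome II, a run of microRNA genes of the early embryo, lay under a single wide peak (11537490 to 11538452, signal 225). The summit at 11537656 was within 200 bp of cel-mir-35, cel-mir-36 and cel-mir-37. Further summits of the same peak lay at 11537873 (165.7) and 11538110 (56.91). The cluster sits on the strand opposite to Y62F5A.9, in whose intron the first summit falls. Replicate 1 ranked its highest peak there 15 and replicate 2 ranked it 26.

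**Figure D1:**
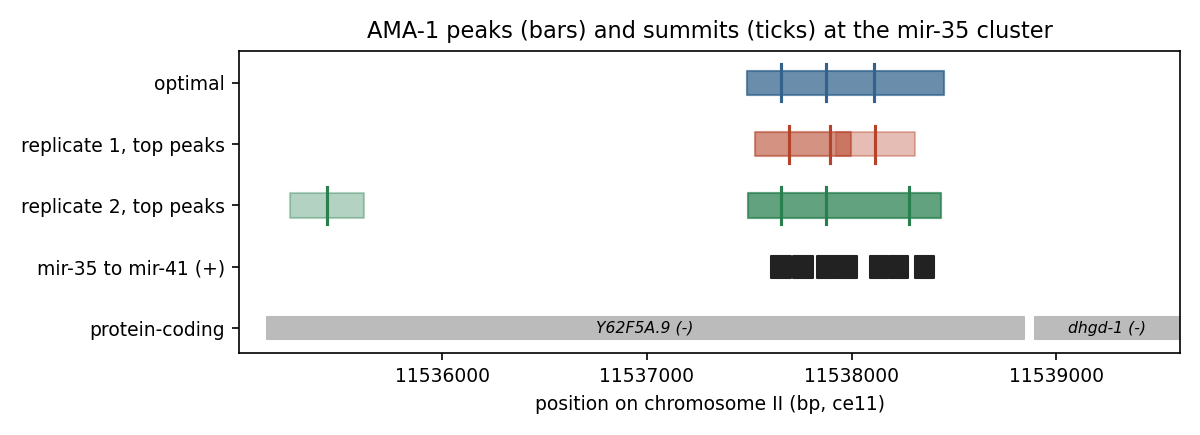
AMA-1 peaks (bars) and summits (ticks) over the mir-35 cluster on chromosome II, in bp of ce11, for the optimal list and for the top 724 peaks of each replicate, with the microRNA genes (black) and protein-coding genes (grey) under them. The optimal peak from 11537490 to 11538452 carries 3 summits and covers the cluster from cel-mir-35 to cel-mir-41.

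The replicates shared many of their highest sites and ordered them only partly alike. Of replicate 1's top 724 peaks, 280 (38.7%, 35.1 to 42.3) overlapped replicate 2's top 724, against a mean of 4.03 for shifted peaks and at most 60 in any shift (p = 1.00e-04, one-sided permutation, the smallest possible). In the other direction 275 (38%) overlapped. Among optimal peaks, 676 (93.4%, 91.3 to 95.1) overlapped the upper 5000 peaks of both replicates and 0 were missing from both. This share has no test because the optimal list was built from the same libraries. Across 2468 overlapping pairs, signal had a Spearman's rho of 0.323 (0.287 to 0.358), where peaks are not independent replicates.

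Some high peaks belonged to 1 replicate. In each replicate, 103 of the top 724 peaks (14.2%) had no overlapping peak in the upper 10000 of the other, and 36 of replicate 1 and 31 of replicate 2 had none in all 30000. The collagen gene sqt-3 ranked 261 in replicate 1 and 14049 in replicate 2. The summit shared by the histone genes his-7 and his-8, named after its values were seen, ranked 13762 in replicate 1 and 44 in replicate 2. Both replicates used the same control, so its noise is common to them. The targeted gene, ama-1 (IV, 4248070 to 4258169), had no optimal peak: its best peak ranked 2206 in the pooled list, 2066 in replicate 1 and 1932 in replicate 2.

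Chromosome X and chromosome V carried fewer AMA-1 peaks than their length would give. X had 65 peaks, or 3.67 per Mb, which was 8.98% of peaks (7 to 11.3) on 17.7% of the length (p = 4.76e-11, adjusted p = 2.85e-10, two-sided exact binomial test). V had 98 peaks, or 4.68 per Mb (13.5% on 20.9% of the length, adjusted p = 1.33e-06, exact binomial test). Chromosomes I (143 peaks, 9.49 per Mb, adjusted p = 8.78e-04), II (141, 9.23 per Mb, 0.002683) and III (133, 9.65 per Mb, 8.78e-04) lay above their share by the same exact test, and IV did not differ (144, 8.23 per Mb, adjusted p = 0.08648).

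Genes on X were also bound less often. On X, 34 of 2731 protein-coding genes were bound (1.24%, 0.864 to 1.74), against 478 of 17242 autosomal genes (2.77%, 2.53 to 3.03), a ratio of 0.449 (p = 4.39e-07, two-sided Fisher's exact test). The dosage compensation complex acts on X in XX embryos, and X is silenced in the germline, which makes X a standard comparison for RNA polymerase II in this species. Within X, bound genes included the linker histone genes his-24 and hil-3, the junction gene dlg-1 and the spectrin gene spc-1. Chromosome V had 81 of 4994 genes bound (1.62%, 1.29 to 2.01) and chromosome I 110 of 2878 (3.82%, 3.15 to 4.59). On each replicate's own top 724 peaks, the share on X was 10.5% in replicate 1 and 9.25% in replicate 2.

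AMA-1 summits concentrated in exons, 3' UTRs and the first 500 bp past genes, and were scarce in introns and away from genes. Exons (5' UTR or coding) held 323 summits (44.6%, 41 to 48.3) against 25.6% for shifted summits, a ratio of 1.75. The 3' UTR class held 41 (2.12 times the shifted mean of 19.3) and the downstream class 85 (2.8 times 30.4). Introns held 154 (0.633 times 243) and positions away from genes 38 (0.214 times 178). Each of these gave p = 2.00e-04, the smallest a two-sided circular-shift permutation allows, and an adjusted p of 2.40e-04. The class within 500 bp upstream held 83 summits against 68.1 (ratio 1.22, permutation p = 0.07799) and was not called.

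The upstream class passed the threshold in the upper 362 optimal peaks, at 1.57 times its shifted mean (p = 0.0024, permutation). Classes were assigned in a fixed order, so a summit past the end of 1 gene counts for a close neighbour's upstream, exon or intron class where these overlap.

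**Figure D2:**
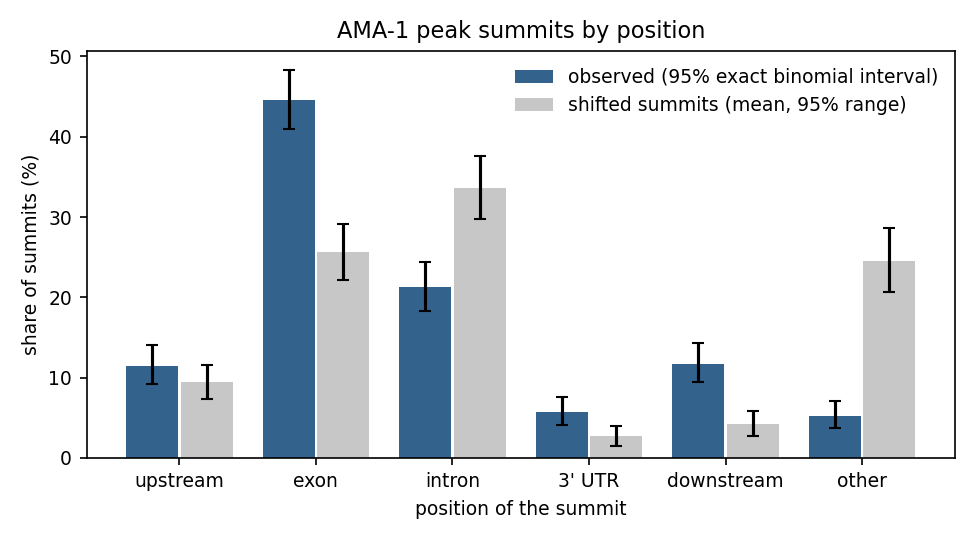
Share of the 724 optimal summits in each position class (blue, % with 95% exact binomial intervals) beside the mean and 95% range of circularly shifted summits (grey). Exons hold 44.6% of summits against 25.6% after shifting, and the downstream class 11.7% against 4.19%.

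AMA-1 summits gathered near both ends of protein-coding genes within 250 bp. In that window, 171 summits lay at a 5' end (2.42 times the shifted mean of 70.5) and 164 at a 3' end (2.55 times 64.4), each with permutation p = 2.00e-04, the smallest possible. The difference of 7 did not differ from the 6.15 given by shifted summits (p = 0.9651, two-sided permutation). With a window of 100 bp, 5' ends held 52 summits (1.8 times 28.9, permutation p = 6.00e-04) and 3' ends 36 (1.35 times 26.7, permutation p = 0.09459), and the 3' side was not called. Among the 509 summits inside a single gene, 163 fell in the first of 4 equal parts of the gene, 85 in the second, 97 in the third and 164 in the last. With a window of 500 bp the balance turned to the 3' side, with 287 summits at 5' ends and 404 at 3' ends (difference -117, permutation p = 2.00e-04, the smallest possible).

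The 3' accumulation lay mostly past the annotated ends. In 100 bp bins chosen after the summits had been examined, 93 summits fell 300 to 399 bp past the nearest 3' end, against a shifted mean of 12 (7.77 times). The adjoining bins held 86 summits at 200 to 299 bp (6.84 times) and 54 at 400 to 499 bp (4.71 times), and the bin that starts 100 bp past the end held 63 (4.76 times). On the 5' side the highest bin was 200 to 299 bp inside the gene, with 76 summits against 14.3 (5.31 times). In all, 296 of 724 summits (40.9%) lay 100 to 500 bp past a 3' end, 6 times the shifted mean of 49.4, with 226 in replicate 1's top 724 and 286 in replicate 2's. The same distance before a 3' end held 73 summits, 1.52 times the shifted mean of 48.1, with a permutation p below the threshold, as in replicate 1 (1.35 times, permutation p = 0.0238) and replicate 2 (1.54 times, permutation p = 6.00e-04). By the fixed order of classes, 132 of the 296 counted as exon, 43 as upstream and 40 as intron of another transcript or gene, 72 as downstream and 9 as 3' UTR.

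Named after their values were seen, genes with high summits there were the HMG-box gene hmg-1.1 (II, rank 28, signal 173.3, 216 bp past the end), the RNA-binding protein gene hrpa-1 (IV, rank 39, 143.7, 271 bp), the splicing kinase gene spk-1 (III, rank 60, 116.3, 261 bp), the acetyltransferase gene cbp-1 (III, rank 114, 91.44, 397 bp) and the histone variant gene htz-1 (IV, rank 132, 87.5, 135 bp). The hrpa-1 summit also lay in an exon of F42A6.6, 224 bp inside its 5' end, the spk-1 summit in an exon of B0464.6 and the htz-1 summit upstream of chat-1, so these 3 cannot be assigned to 1 gene. The highest summits past 3' ends were peaks already given above: sls-2.4 (rank 2, 137 bp past R12E2.11), sls-2.1 (rank 3, 306 bp past nep-25) and his-31 (rank 23, past lys-10).

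**Figure D3:**
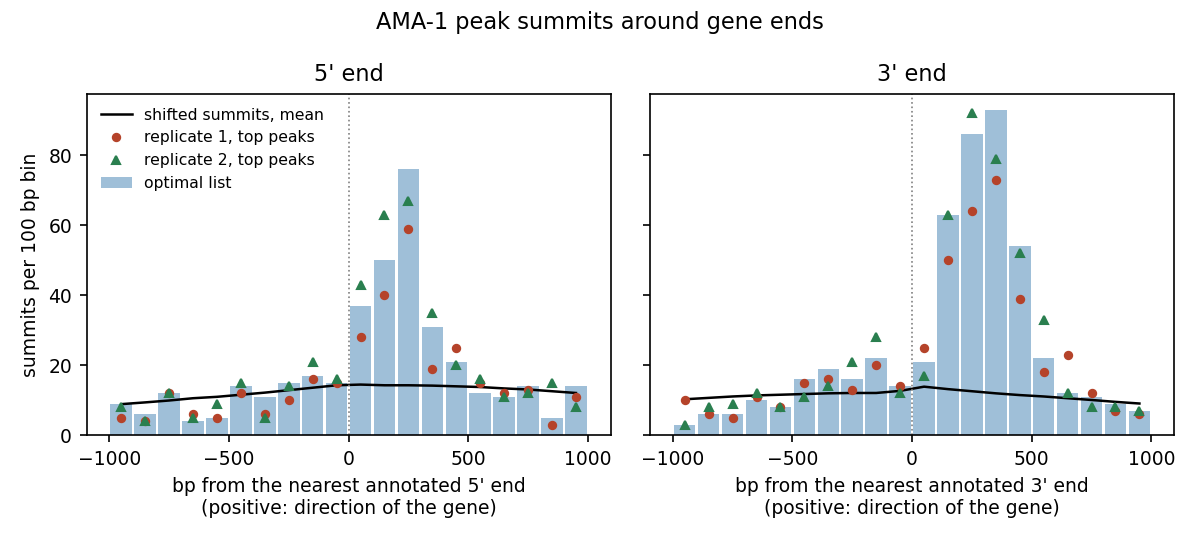
AMA-1 summits per 100 bp bin by distance in bp from the nearest annotated 5' end (left) and 3' end (right) of a protein-coding gene, for the optimal list (bars), for the top 724 peaks of each replicate (points) and for the mean of shifted summits (line). The tallest 3' bin of the optimal list and of replicate 1, 300 to 399 bp past the end, holds 93 and 73 summits. Replicate 2 has 79 there, and its tallest 3' bin is 200 to 299 bp past the end, with 92.

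Histone genes and chaperone genes had the highest bound shares of the gene lists on the optimal peaks. Of 72 histone genes 21 were bound (29.2%, 19 to 41.1), 11.8 times the 2.47% of other protein-coding genes (adjusted p = 1.00e-15, Fisher's exact test). The share was 26.4% ± 3.93 (SD, n = 2) on the replicates' own top peaks. Core histone genes his-32, his-59 and his-60 and the linker histone gene his-24 carried the highest signals of the list. Summits were shared by divergent pairs such as his-59 with his-60, so both genes of such a pair counted as bound. The ratio was 10.7 with genes matched on length (adjusted p = 0.0017, permutation), 5.14 in the upper 2000 pooled peaks and 21.4 in the upper 362 optimal peaks. In 48 of the 72 histone genes under 50% of 31-mers occur once in the genome, so individual histone genes, and the unbound ones above all, are uncertain. The order of the lists changed with the setting: in the upper 2000 pooled peaks cytoskeleton and junction genes stood highest (41.2%, against 36.8% for chaperone and 31.9% for histone genes), and with summits in a single gene's window the shares were 21.1% for chaperone, 18.1% for histone and 17.6% for cytoskeleton and junction genes.

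Chaperone genes were bound in 11 of 38 cases (28.9%, 15.4 to 45.9), 11.5 times other genes (adjusted p = 1.54e-08, Fisher's exact test; 11 times with matched lengths, adjusted p = 0.0017). On the own peaks of replicates 1 and 2, 12 and 7 members were bound (25% ± 9.3, SD, n = 2), which put the ratio at 12.8 and 7.17, and it was 5.89 in the upper 2000 pooled peaks. The highest were hsp-12.3, a small heat shock protein gene (IV, 3' UTR, signal 135.7), hsp-1, the constitutive Hsp70 (IV, exon, 95.85), dnj-12, an Hsp40 gene (I, exon, 85.6), and hsp-90 (V, exon, 84.28). The hsp-12.3 summit also lay within 200 bp of the snRNA gene F38E11.11. Named after their values were seen, the others were crt-1 (calreticulin), dnj-13, cct-7 (a subunit of the cytosolic chaperonin), pdi-2, hsp-110 and the divergent heat-inducible pair hsp-16.2 and hsp-16.41, which shared 1 summit.

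Cytoskeleton and cell junction genes were bound in 6 of 34 cases (17.6%, 6.76 to 34.5), 6.95 times other genes (adjusted p = 0.00114, Fisher's exact test; 5.14 times with matched lengths, adjusted p = 0.0136). The share was 20.6% ± 4.16 (SD, n = 2) on the replicates' own peaks. Bound members included unc-70 (beta-spectrin; V, intron, signal 101.8), hmr-1 (I, intron, 74.12), dlg-1 (X, intron, 60.35) and spc-1 (alpha-spectrin; X, exon, 58.48). Their summits lay far inside the gene, 7616 bp from the 5' end in unc-70 and 48380 bp in hmr-1. Only the outermost 5' end of each gene was used, so starts of shorter transcripts inside a gene were not considered. A window of 500 bp around the 5' end held 0 of the 34, and the call was lost in the upper 362 peaks (ratio 4.25, adjusted p = 0.3441, Fisher's exact test).

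Cytosolic ribosomal protein genes were bound in 7 of 83 cases (8.43%, 3.46 to 16.6), 3.32 times other genes (adjusted p = 0.02303, Fisher's exact test; 3.63 times with matched lengths, adjusted p = 0.02295). The highest were rps-26 (I, 96.97), rpl-27 (I, 94.94), rpl-3 (III, 78.15) and rps-11 (IV, 76.18). The rps-26 and rps-11 summits lay 433 and 411 bp upstream, and the rps-26 summit also lay within 200 bp of the snoRNA gene F39B2.14. The rpl-3 summit also lay 163 bp past the 3' end of tir-1. The call was lost on either replicate's own peaks, where 6 members were bound (ratios 2.8 and 2.9, adjusted p = 0.07137 and 0.06169), and without summits near noncoding RNA genes (3.13, 0.0548), an exact test added after the data had been seen.

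No other list was called on the optimal peaks with gene windows. Early zygotic regulators had 3 of 58 bound, namely die-1 (signal 74.44), sdz-19 (67.21) and nhr-2 (56.52), and maternal and germline factors 3 of 57, namely cpg-1 (56.16), skn-1 (55.55) and mbk-2 (52.42). The bound translation factors were eif-3.C (70.78) and eef-1B.2 (56.59), 2 of 42, and the bound proteasome subunit was rpn-6.1 (52.13), 1 of 33. Respiratory chain genes had 3 of 60 (ndub-2, 60.32, nuo-4, 56.02 and cyc-2.1, 51.22) and cell cycle genes 3 of 47 (cye-1, 89.69, rnr-2, 86.46 and cki-1, 59.96). Dosage compensation and sex determination had 1 of 25, the condensin gene mix-1 (108.5), whose summit also lay near the snoRNA gene M106.6, and RNA polymerase II and general transcription 1 of 43, taf-4 (93.71). The sdz-19 summit also lay 274 bp past the 3' end of scd-1, the eif-3.C summit 194 bp past sys-1 and the eef-1B.2 summit 122 bp past fcd-2. Likewise, the ndub-2 summit lay 327 bp past F44G4.1 and 429 bp past F44G4.3, and the cyc-2.1 summit 375 bp past rpl-20. These summits cannot be assigned to 1 gene. Some counts of these lists differed on the replicates' own top peaks. Respiratory chain genes had 1 of 60 in each (0.662 times other genes in replicate 1 and 0.641 in replicate 2). Cell cycle genes had 3 in replicate 1 and 6 in replicate 2, where the list was called (4.96 times, adjusted p = 0.005527, Fisher's exact test). Dosage compensation and sex determination had 4 in replicate 1, where it was called (6.41 times), and 2 in replicate 2, translation factors 3 and 2, and general transcription 1 and 2.

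None of the lists of differentiated tissues differed from other protein-coding genes by Fisher's exact test. The bound share was 2.78% for body wall muscle, 2% for neurons and 1.59% for collagen and cuticle, against 2.56% to 2.57% of other genes. Body wall muscle had 1 of 36 (dys-1, 59.58), neurons 1 of 50 (mec-17, 65.7) and collagen and cuticle 3 of 189 (dpy-17, 77.22, col-99, 64.13 and sqt-3, 51.9). The dys-1 summit also lay 432 bp past the 3' end of phm-2, the mec-17 summit 401 bp past arf-5 and the dpy-17 summit 298 bp past F54D8.6. These summits cannot be assigned to 1 gene. On the own peaks of replicates 1 and 2, muscle had 1 and 0, neurons 2 and 0, and collagen and cuticle 4 and 3. The intestine had 0 of 44 (up to 8.04%) and sperm 0 of 64 (up to 5.6%), with adjusted p values from 0.7056 to 1 over these lists.

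**Figure D4:**
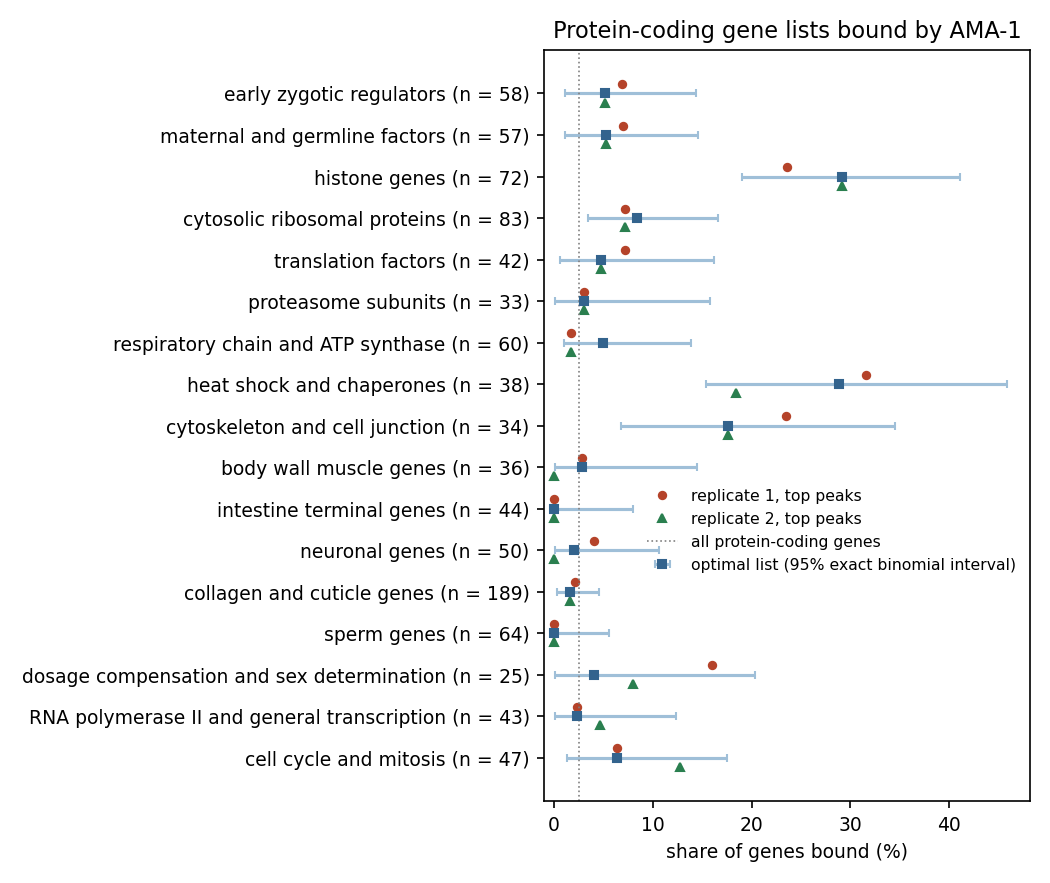
Share of each gene list's members bound by AMA-1 (%), from the optimal list (squares, 95% exact binomial intervals) and from the top 724 peaks of replicate 1 (circles) and replicate 2 (triangles), with the share of all protein-coding genes as a dotted line at 2.56%. Histone genes (29.2%) and chaperone genes (28.9%) stand highest.

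Genes for the SL2 spliced leader RNA, snRNA genes as a class, microRNA genes and snoRNA genes carried AMA-1 summits far more often than shifted summits gave. Of 18 sls-2 genes, 11 were bound (61.1%, 35.7 to 82.7; 61.1% ± 7.86, SD, n = 2 on the replicates' own peaks), 134 times the shifted mean. The snRNA genes, which include the sls-2 genes and those of the splicing machinery, had 20 of 129 bound (15.5%, 9.73 to 22.9; 40.4 times). The 11 sls-2 genes are among these 20, and the class without them was not tested. MicroRNA genes had 27 of 261 (10.3%, 6.93 to 14.7; 30.6 times) and snoRNA genes 30 of 346 (8.67%; 7.23% ± 2.45, SD, n = 2 on the replicates' own peaks; 21.1 times, and 13.5 times on replicate 1's own peaks). A summit in a cluster counts for several microRNA genes, and 19 summits accounted for the 27. The 29 snoRNA summits were not split by whether they also lay in a protein-coding window, as those at rps-26 and mix-1 did. Of all optimal summits, 83.3% lay in such a window, and shifting does not keep summits near genes. The snoRNA ratio therefore need not reflect the snoRNA genes themselves. Each class gave an adjusted p of 3.14e-04, from the smallest p the circular-shift permutation allows. The ratios moved with the length of the list, for snRNA genes from 18.2 in the upper 2000 pooled peaks to 70.5 in the upper 362 optimal peaks and for tRNA genes from 3.84 to 15.8.

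Transfer RNA genes, which RNA polymerase III transcribes, were bound in 15 of 612 cases (2.45%, 1.38 to 4.01), 8.71 times the shifted mean (adjusted p = 3.14e-04, permutation). Of their 14 summits, 9 also lay in a protein-coding window, 1 near another short RNA gene and 4 in neither, where 83.3% of all optimal summits lay in a protein-coding window. Genes for piRNAs (5 of 15363, 0.0983 times) and pseudogenes (5 of 2128, 0.215 times) were bound less often than shifted summits gave, with the same adjusted p. On their own top peaks replicate 1 gave 13 piRNA genes (0.272 times) and replicate 2 gave 4 (0.0783 times), and for pseudogenes they gave 4 and 5. Long intergenic RNA genes (2 of 194), antisense RNA genes (0 of 100, up to 3.62%) and rRNA genes (0 of 20, up to 16.8%) did not differ. For the SL1 spliced leader genes, 0 of 12 (up to 26.5%) were bound. In all 12, under 50% of 31-mers occur once in the genome (median 0%), so the value says nothing about their occupancy.

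**Figure D5:**
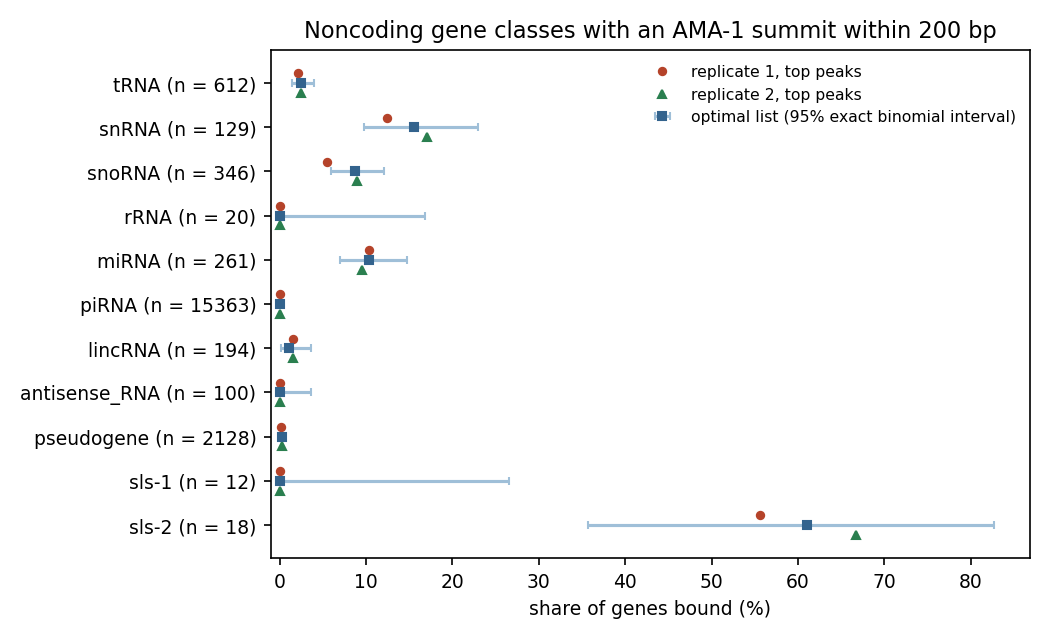
Share of genes in each noncoding class with an AMA-1 summit within 200 bp (%), from the optimal list (squares, 95% exact binomial intervals) and from the top 724 peaks of replicate 1 (circles) and replicate 2 (triangles). The sls-2 genes stand at 61.1%, snRNA genes at 15.5% and tRNA genes at 2.45%.

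The same libraries gave 724 optimal peaks on ce11 and 812 on ce10. Chromosome shares were close on both builds: X held 8.98% of peaks on ce11 and 9.24% on ce10, and V held 13.5% and 13.1%. On ce10, 744 optimal peaks (91.6%, 89.5 to 93.4) overlapped the upper 5000 of both replicates. The counts have no test, since both builds rest on the same reads.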

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

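Assignment of summits past 3' ends to the gene lists and removal of summits near noncoding RNA genes were chosen after the results had been seen, while the other settings were chosen beforehand. Of the recomputed values that answer a comparison, 181 kept their direction and side of the threshold or moved by less than their interval, 7 moved further (among them the number of called lists, from 4 to 8 and to 7 past 3' ends), 5 gained a call, 8 lost one and 2 changed direction across the threshold. The 400 values in all include those that answer no comparison. In 25 cases the ratio of an uncalled list crossed 1 without a call. The lower share of X, the exon, intron, 3' UTR and downstream classes, the histone and chaperone lists and the called noncoding classes kept their calls under every setting run for them. No ce10 length test of X was run, and no paired analysis was possible because the samples form 1 group. Where a value changed, the cause was not tested, except that fewer or more peaks enter some settings by construction.

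Optimal peaks found in both replicates were 37.7% among the top 724 of each, 97.9% among the top 10000, 75.8% when 50% of both peaks had to overlap and 77.9% for summits within 100 bp. Spearman's rho was 0.397 in the upper 1000. The upstream class passed the threshold at 1.57 in the upper 362 peaks, at 1.24 with merged peaks (p = 0.05 after rounding, permutation) and at 1.19 with windows of 1000 bp. On single replicates it ranged from 0.98 to 1.25, passing on replicate 2 alone. The 5' minus 3' difference passed at 55 in the upper 2000 pooled peaks and turned to -117 with a window of 500 bp. The cytoskeleton list fell to 4.25 in the upper 362 peaks and to 0 with a window of 500 bp around 5' ends, losing its call both times. The ribosomal protein list lost its call at 1.92 in the upper 2000 pooled peaks, 2.86 by peak region, 2.58 by nearest 5' end, 2.65 with summits in a single gene's window, 3.13 away from noncoding RNA genes and 2.8 to 2.9 on single replicates.

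Other lists gained a call under some settings. The cell cycle list was called at 3.73 in the upper 2000 pooled peaks, 4.96 on replicate 2 alone, 5.06 by peak region and 3.8 by nearest 5' end. Dosage compensation and sex determination was called at 6.41 on replicate 1 alone and translation factors at 4.25 by nearest 5' end. With summits 100 to 500 bp past a 3' end, 8 lists were called against 4 with gene windows, and RNA polymerase II and general transcription turned from below to above other genes at 5.45. Without summits near noncoding RNA genes, 7 lists were called there and that list stood at 5.96. Read depth is unknown, so whether peaks missing from 1 replicate reflect fewer reads could not be tested.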

Other observations

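The gene lists past 3' ends and the tests of histone and short RNA genes by single-copy sequence as the whole cause, of transfer RNA genes, of histone genes downstream, of heat stress, of rank, of the middle of the chromosomes and of the builds were chosen after the results were seen. Single-copy sequence at summits, noncoding RNA genes lying downstream and 5' ends of neighbouring genes were tests fixed before their results were seen.

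Some cell cycle and mitosis genes had an AMA-1 summit just past their 3' ends, mostly in replicate 2. When a gene was counted by a summit 100 to 500 bp past its 3' end, 10 of 47 cell cycle and mitosis genes were bound (21.3%, 10.7 to 35.7), 12.7 times other protein-coding genes (adjusted p = 1.01e-07, Fisher's exact test). They were top-2 (topoisomerase II, signal 106.8), rnr-2 and rnr-1 (ribonucleotide reductase, 98.89 and 54.36), icp-1 (85.11) and air-1 (54.73) of mitotic kinase complexes, smc-4 (condensin, 73.62), cyk-4 (cytokinesis, 59.97), mcm-5 (57.22) and mcm-7 (55.34) of the replicative helicase, and spd-2 (centrosome, 51.6). The summits of rnr-2, icp-1, smc-4, cyk-4, mcm-5, mcm-7 and spd-2 also lay in the window of a neighbouring protein-coding gene. Replicate 2's own top 724 peaks gave 11 such genes and replicate 1's gave 2, a difference that was not tested. The top-2 summit also lay near cel-mir-45, and 9 genes were left without summits near noncoding RNA genes (12.5 times, adjusted p = 7.37e-07, Fisher's exact test). With the gene window alone, 3 of the 47 were bound.

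Another 7 lists were called by summits past 3' ends. Chaperone genes had 8 of 38 (12.5 times, adjusted p = 1.89e-06), cytoskeleton and junction genes 7 of 34 (20.6%, 8.7 to 37.9; 6.84e-06) and ribosomal protein genes 10 of 83 (7.17 times, 6.84e-06), by the same exact test. Translation factors had 5 of 42 (7 times, 0.002523; 3 on each replicate's own peaks), general transcription genes 4 of 43 (taf-4, rpb-9, spt-5 and spt-16; 5.45 times, 0.01782), histone genes 5 of 72 (4.08 times, 0.01951) and proteasome subunits 3 of 33 (5.32 times, 0.04009), again by the exact test. The 4 general transcription genes rested on replicate 2, whose own peaks gave 5 against 0 in replicate 1. The histone call leaned on replicate 2 too, with 8 genes against 1 in replicate 1. The proteasome call was lost without summits near noncoding RNA genes (3.86 times, adjusted p = 0.1617, Fisher's exact test). In the intestine, neuron, collagen and sperm lists 0 genes were bound this way, against 1.73% to 1.74% of other genes, and none of these lists differed by the exact test (adjusted p from 0.1308 to 1). The replicates' own peaks gave 1 collagen gene each, and replicate 2's gave 1 sperm gene. Respiratory chain genes (3 of 60), dosage compensation (2 of 25), muscle (2 of 36), maternal (2 of 57) and early zygotic genes (1 of 58) were not called. A single summit between the repeated hsp-16.48 copies on V, at 9088997, counts for both copies; its own surroundings are 100% single-copy, whereas the hsp-16.48 and hsp-16.1 copies there are 0% single-copy.

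Peaks at short RNA and histone genes may owe something to reads of near-identical copies. The design holds 1 group, so no biological explanation was tested. As the whole cause at microRNA genes, copies are argued against by 27 of 252 mostly single-copy ones bound (10.7%, 7.18 to 15.2). Shifted summits gave 0.883 for all 261 microRNA genes. At histone genes, 62.5% (40.6 to 81.2) of 24 mostly single-copy ones were bound, against 2.47% of other genes. With snRNA genes added to the microRNA genes, 47 of 341 were bound, where shifted summits gave 1.19. For snRNA and histone genes these values cannot decide, since 100 bp flanks enter the single-copy share and can carry a repeated short gene past 50%. A part in the pattern stays open: around summits the median share of single-copy 31-mers was 100% at short RNA genes but with a lower quartile of 79.5%, and 69.6% at histone genes (quartiles 34.5 and 76). Unspecific enrichment of any active short RNA gene, those of RNA polymerase III included, is a technical explanation that stays open. Among mostly single-copy genes, 2.56% (1.44 to 4.18) of tRNA genes were bound against 22.5% of snRNA and 10.7% of microRNA genes. The single-copy share counts 100 bp on each side of a gene, and its median over tRNA genes was 77.8%. Reads lost over repeated tRNA sequence could therefore lower their bound share, and the comparison cannot decide. How active the tRNA genes were was not measured.

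Summits past 3' ends could reflect what lies next to the gene, and no biological explanation was tested. Noncoding RNA genes of the tested classes lying downstream are argued against as the whole cause of the downstream class of 85 summits. Without summits near them the downstream class stood at 2.52 times its shifted mean. Summits near the annotation's unspecified ncRNA class were not removed, so the part of those genes stays open. Histone genes, whose ends lie close together, are likewise argued against for that class (2.78 times without summits within 500 bp of them, which left 81 of the 85). The position test of all 296 summits past 3' ends was not repeated without either set. Promoters of close protein-coding neighbours are argued against as the whole cause of summits past 3' ends. Of these summits, 131 lay over 500 bp from the outermost 5' end of every protein-coding gene. That was 3.99 times the shifted mean (permutation p = 2.00e-04, the smallest possible). Summits near noncoding RNA genes were not removed from the 131, and starts inside genes were not considered, so both stay open. All 296 summits stood at 6 times their shifted mean, and most of them lay within 500 bp of a protein-coding 5' end. A part played by neighbours therefore stays open. Unannotated starts, trans-splice sites far from the true start, and annotated 3' ends that stop short stay open as untested.

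The larger optimal list on ce10 (812 against 724 peaks) could come from the lists that entered the IDR procedure, and no biological explanation was tested. Signal values of the pooled lists matched by rank differed by a median of 0.00596% between builds, but this cannot show which locus holds which rank, so a changed ranking of pooled peaks stays open. A changed list for replicate 1 remains a candidate cause: its values differed by a median of 0.443% against 0.0137% in replicate 2, and its most common peak width was 380 bp on ce10 and 384 bp on ce11, while replicate 2 had 364 bp on both. The IDR step itself was not rerun.

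Another 3 hypotheses stay open. Higher peaks may lie nearer to noncoding RNA genes: 19.6% of the upper 362 optimal peaks did against 6.91% of the lower 362, a ratio of 2.84, but these are the peaks that prompted the idea, so they cannot test it. Heat stress at collection could raise chaperone genes. Strongly heat-inducible members (2 of 7) and the others (9 of 31) gave p = 1 by Fisher's exact test, too few genes to decide. The 2 bound, hsp-16.2 and hsp-16.41, shared 1 summit, and the hsp-16.1 and hsp-16.48 copies are not single-copy. Those copies counted as unbound, although a summit at V 9088997 (rank 41, signal 143.5) lay between the hsp-16.48 copies. The contrast therefore cannot decide. Gene density might place peaks in the middle of chromosomes: the central of 3 equal parts holds 40.9% of summits and 37.8% of genes (ratio 1.08), yet genes there were bound slightly more often (2.85% against 2.39%, p = 0.04717, Fisher's exact test), and on III (30.1% against 40.3% of genes) and X (32.3% against 35.8%) the order was the opposite, which leaves this open. Outside the tested classes, genes of the annotation's unspecified ncRNA class were bound in 80 of 7764 cases, 2.96 times the shifted mean (p = 2.00e-04, the smallest possible, permutation).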
